A study of Mus musculus with 8 samples.

How the data were processed

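Total RNA (50 ng per sample, per the labels' protocols) from sorted CD4+CD25+ GFP-RFP+ and GFP+RFP+ cells of the lymph nodes and spleens of 20 mice was labelled with biotin and hybridised to Affymetrix Mouse430_2 arrays. The labels give 4 groups of 2 arrays and call the arrays technical, so a group is 1 RNA pool. Groups and array numbers were taken from the sample titles.

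The values analysed were the deposited intensity of each probe set on a linear scale, 45101 probe sets on 8 arrays, ranging from 0.83 to 10657.04, with column medians from 25.03 to 27.08. The submitters' processing notes name RMA alone. A second deposited table states, per the file headers, model-based expression in dChip with a baseline array and an outlier check, without a log transform. For all 45101 probe sets the 8 values of that table, sorted within the row, were those analysed here, so the linear scale is taken from the values and header, and which of the 2 methods gave the values stays unsettled. The model variant and the normalization step are not given in the sources used here. The 8 signal and 8 call columns of the second table, 16 in all, carry array names that match no sample label and were not used. That table also pairs probe sets with gene identifiers; 37579 probe sets had 1 gene, 1467 several and 5991 none, and 64 were controls. Probe sets with several genes or none were not named. The identifiers gave 20665 genes, of which 18007 took their symbol from an NCBI RefSeq gene table (assembly GRCm38.p6, used for names and no coordinates) and 2658 kept the symbol of the deposited table.

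Values were taken to log2 with no pseudocount and no filter on level. A gene stood for its probe set with the highest mean over the 8 arrays; 9436 genes had several probe sets, and for 140 genes probe sets passed the population test in opposite directions. Background was set at the highest signal of 3 probe sets for a control RNA that is not spiked in, 17.22 (4.11 on the log2 scale), a choice made after the data were seen. Where the mean of a pool was below it, the text gives "at least N-fold" against that level, and no fold when both pools were below. Per array, 12876 to 13340 genes were above it. The ratio of 3-prime to 5-prime signal was 1.178 to 1.347 for actin and 1.149 to 1.283 for Gapdh.

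The population and organ comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on level) on the 4 pool means with organ and population as terms, which leaves 1 residual degree of freedom and a prior of 9.6, with Benjamini-Hochberg adjustment at 0.05. Population differences are GFP-RFP+ minus GFP+RFP+, organ differences are spleen minus lymph node, and errors are standard errors of that fit. Counts at 2-fold came with no test and needed non-overlapping technical arrays. The difference between organs in the population effect was tested on the 8 arrays, against technical spread. Gene lists (21 lists, 328 entries, of which some symbols were not measured) were tested with camera at a preset correlation of 0.01 where 5 or more members were measured, against all other genes, over both directions. The lists were also tested with a correlation estimated over the 4 pools, and over the 8 arrays taken as separate samples. The pool version has 1 residual degree of freedom and called no list even unadjusted. A call lost there does not show that correlation between genes undid it. The 8-array version counts technical arrays as samples, so more than the correlation changes. List medians were ranked among 10000 random lists matched on level. Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots.

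The fits were tested on simulated data for 20665 genes, with independent normal noise whose variance followed the fitted trend on level. No spread of variance around that trend and no correlation between genes were simulated. The simulation therefore does not test the trend prior or the preset correlation. In the population fit a log2 change of 1 was called for 43 of 43 brighter genes and 17 of 57 dimmer genes, a change of 2 for 44 of 44 and 46 of 56, and 7 of 20465 unchanged genes were called. In the interaction fit the calls were 37 of 43 and 4 of 57 for a change of 1, 44 of 44 and 15 of 56 for a change of 2, and 6 unchanged genes. A list of 25 genes shifted by 0.5 had a camera p of 2.23e-28, and 0 of 200 unshifted lists were below 0.05 unadjusted.

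Groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes in each direction for population and 8 for organ with the largest mean log2 difference among those at 2-fold or more the same way in both repeats without overlap of technical arrays. It also took the genes past the interaction test at a log2 size of 1 or more (up to 5 in each direction), all members of the thymic and peripheral Treg lists, Foxp3, and up to 4 members of each other list with the largest absolute difference. Some genes that the rule took are left out of the text, while counts and list tests include them. Genes named outside that rule were chosen after their values were seen; these are Rgs16, genes cited from the count above background in all pools, list members beyond the 4, and all genes in the last part. Alternatives covered the treatment of technical arrays, the trend, the level filter, normalization, probe sets, fold size, the set test, a floor at background and leaving out each array.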

Results

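The data were 8 Affymetrix mouse arrays of regulatory T cells, the CD4+CD25+ cells that express the transcription factor Foxp3 and restrain immune responses. Cells carrying a green (GFP) and a red (RFP) fluorescent reporter were sorted from the pooled lymph nodes and the pooled spleens of 20 untreated mice aged 14 to 17 weeks. The labels call the GFP-RFP+ cells peripherally induced and the GFP+RFP+ cells thymically induced; the title names a definition of both origins by fluorochrome. The 4 groups were the 2 populations in each of the 2 organs, and each group was 1 RNA pool measured on 2 technical arrays. There was therefore no replicate of a group, and the 2 organs were the only repeat of the population comparison. No p-value below holds spread between animals or sorts. For a gene, the population or organ p-value sets the mean difference against a moderated standard error. That error combines 1 residual degree of freedom of the gene with a prior of 9.6 from genes of like level. It therefore rests more on that prior than on how far the 2 organs (or the 2 populations) agreed for the gene. Between technical arrays the signals of the 10332 brighter genes (those with the higher mean level) correlated at 0.9949 and 0.9957 in the lymph node GFP-RFP+ and GFP+RFP+ pools, and at 0.9885 and 0.9951 in those of the spleen. The median technical SD was 0.093 on the log2 scale for the brighter genes and 0.492 for the dimmer rest. The design of 1 RNA pool per group limits the precision, and further technical arrays would hold no spread between animals or sorts.

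The first comparison asked how the peripherally induced population differed from the thymically induced one. GFP-RFP+ cells had far more transcript of Il10, Ifng, Bhlhe40, Areg and Atf3 than GFP+RFP+ cells, in both organs. Il10 (gene ID 16153), an anti-inflammatory cytokine, was 13.9-fold higher in lymph node and 32.5-fold higher in spleen. Its mean log2 difference was 4.41 ± 0.20 (moderated SE of the fit over the 2 organs, limma adjusted p = 1.45e-07). Ifng (gene ID 15978), the cytokine of type 1 responses, was 10.2-fold and 10.6-fold higher (3.38 ± 0.07, adjusted p = 1.23e-09), and the transcription factor Bhlhe40 (gene ID 20893) was 10.3-fold and 15.3-fold higher (3.65 ± 0.10, adjusted p = 5.17e-09). Areg (gene ID 11839), which encodes the epidermal growth factor family member amphiregulin, the stress-induced transcription factor Atf3 (gene ID 11910) and the small Maf protein gene Maff (gene ID 17133) were below background in both GFP+RFP+ pools. They were at least 22.8-fold, 20.3-fold and 17.1-fold higher in GFP-RFP+ cells of lymph node, and at least 39.6-fold, 53.1-fold and 21.3-fold higher in those of spleen, with adjusted p = 1.23e-09, 1.39e-09 and 6.62e-09. Emp1, a membrane protein, was 12.6-fold higher in lymph node and at least 20.9-fold higher in spleen (adjusted p = 6.58e-07). A second, dim Emp1 probe set differed by -0.12 and -0.19. The phosphatase gene Dusp14 was 9.77-fold and 12.8-fold higher, and Gem, a small GTPase gene, was 7.01-fold and 15.0-fold higher. Il21, a cytokine gene of helper T cells, was at least 1.29-fold higher in lymph node and at least 2.71-fold higher in spleen.

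Fewer genes were lower in GFP-RFP+ cells by 2-fold or more at a measurable level. Gsta4 (gene ID 14860), a glutathione transferase, was 4.39-fold lower in lymph node and 5.64-fold lower in spleen (log2 difference -2.32 ± 0.12, adjusted p = 3.08e-07). Gpr83 (gene ID 14608), a receptor long used as a regulatory T cell marker, was 3.44-fold and 4.08-fold lower (-1.91 ± 0.07, adjusted p = 2.09e-08). Khdc1a was at least 3.43-fold lower in lymph node and 3.56-fold lower in spleen. The other genes that the naming rule took in this direction, Chil3, Cfhr3, Pnmt, Ptchd3, Medag, Slc16a11 and Ldhal6b, lay at or close to background in both populations, and their bounds reached at most 1.28-fold. Among genes above background in all 4 pools, a restriction made after the values were seen, 223 genes were at least 2-fold higher in both organs and 25 were lower. The 25 included Gata1, a haematopoietic transcription factor (-1.55 ± 0.11), Ctsw, a cathepsin of cytotoxic lymphocytes (-1.40 ± 0.08), and Mbnl3 (-1.05 ± 0.06). The 223 included Cxcl10 (3.03 ± 0.08) and Cxcl2 (3.29 ± 0.14), which encode chemokines, the cell cycle inhibitor gene Cdkn1a (3.15 ± 0.16) and the circadian clock gene Per1 (2.53 ± 0.07).

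**Figure D1:**
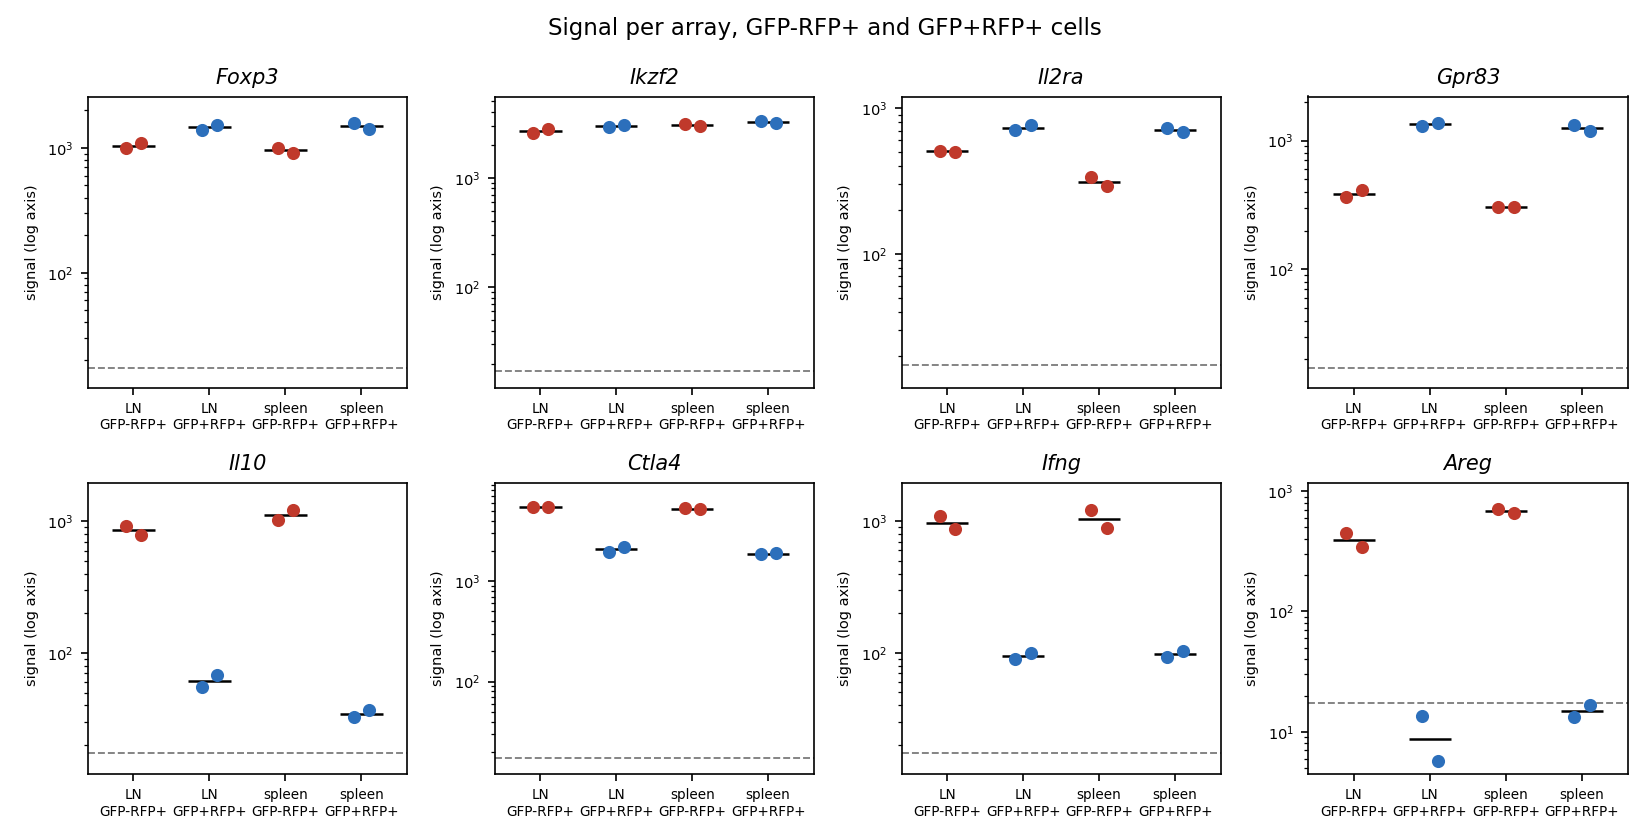
Signal of 8 genes on each of the 8 arrays, on a log axis, with 2 technical arrays (points) and their geometric mean (bar) for each population in lymph node (LN) and spleen; the dashed line is the background level of 17.22. Il10, Ctla4, Ifng and Areg lay higher on every GFP-RFP+ array than on every GFP+RFP+ array of either organ, Foxp3, Il2ra and Gpr83 lay lower, and Ikzf2 differed by 0.16 or less on the log2 scale in either organ.

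Over the 20665 genes tested, 3272 passed an adjusted p of 0.05, 1968 higher and 1304 lower in GFP-RFP+ cells. Of these, 425 were higher and 126 lower by a mean log2 difference of 1 or more. Without a test, 1564 genes differed by 2-fold or more with no overlap of technical arrays in lymph node (900 higher, 664 lower) and 1579 in spleen (913 higher, 666 lower). On the brighter genes alone the splits were 258 higher and 34 lower in lymph node, and 307 and 59 in spleen. Over all 20665 genes, 442 differed by 2-fold or more the same way in both organs, 350 higher and 92 lower. Independent lists would share 39.8 and 21.4. Another 73 went opposite ways, and 98 of the 442 had no pool above background. The test leaned on the level-dependent prior of limma: without that trend 0 genes passed, with 3479 at an unadjusted p under 0.05 and a smallest adjusted p of 0.254. With quantile normalization added the split was 1517 higher and 1805 lower of 3322, and without the spleen GFP-RFP+ replicate 1 array 2116 genes passed.

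Effector genes of regulatory T cells rose together in the GFP-RFP+ cells. Of the 28 measured members of the list of activated and effector Treg genes, 25 rose and 0 fell, over all genes tested as well as adjusted over the list alone, and the median log2 difference was 1.18 (1.10 in lymph node, 1.26 in spleen). Besides Il10, Gzmb, which encodes the cytotoxic protease granzyme B, was 5.26-fold and 5.65-fold higher, the receptor gene Klrg1 3.81-fold and 4.25-fold, and the calcium-binding protein gene S100a6 3.32-fold and 3.28-fold. Transcription factors on the list that rose included Rora (1.62 ± 0.08), Prdm1 (1.40 ± 0.09), Irf4 (1.35 ± 0.09), Maf (0.92 ± 0.06) and Gata3 (0.73 ± 0.06), named after their values were seen. Havcr2 (0.01), Pdcd1 (0.11) and Tnfrsf9 (0.13) did not pass. The list ranked above all other genes with a preset correlation (limma camera, adjusted p = 1.92e-32). It also did so with a correlation estimated over the 8 arrays (adjusted p = 0.0198), a test that takes technical arrays as samples. The call was lost with an estimated correlation over the 4 pools (adjusted p = 0.466), a test with 1 residual degree of freedom. That test called no list of either comparison, also where the estimated correlation was below the preset 0.01 (-0.039 for T helper lineage genes). For the effector list itself the estimates were far above the preset, at 0.492 over the pools and 0.206 over the 8 arrays. Its p with the preset correlation rests on a value below both estimates.

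Genes for suppressive molecules followed the same direction, with 10 of 13 measured members higher and 0 lower (the same counts adjusted over the list alone; median 1.04, or 0.78 with signals under background set to it). Lag3, an inhibitory receptor gene, was 2.98-fold and 3.16-fold higher, and Areg, Il10 and Gzmb were also on this list. Tgfb1 differed by 0.00 ± 0.09, Entpd1 by -0.07 ± 0.09 and Prf1 by -0.21 ± 0.16, and none of the 3 passed. The list test gave an adjusted p of 1.05e-11 with the preset correlation, 0.0119 with one estimated over the 8 arrays, and lost the call with an estimated correlation over the pools (adjusted p = 0.466). Of 18 costimulatory and inhibitory receptor genes, 7 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.09. Ctla4, the inhibitory receptor central to Treg function, was 2.64-fold and 2.82-fold higher and the costimulator Icos 2.27-fold and 2.63-fold, while Tnfrsf25 (-0.43 ± 0.06) and Cd27 (-0.32 ± 0.05) fell. This list's median was at percentile 81.9 among random lists, and it had a camera adjusted p of 0.00133, which was lost with an estimated correlation (adjusted p = 0.466 over the pools and 0.197 over the 8 arrays).

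Genes that define helper T cell lineages were mostly higher in the GFP-RFP+ cells, with 14 of 22 measured members up and 0 down (17 and 1 adjusted over the list alone). The median was 0.89, or 0.60 with signals under background set to it, because 9 members were below background in at least 1 pool. Beside Il10, Ifng and Il21, the lineage regulators Tbx21 (1.19 ± 0.10), Ahr (1.18 ± 0.06), Bcl6 (0.88 ± 0.07) and Gata3 rose, chosen for mention after their values were seen. Il13 passed, but it was below background in 3 pools and at least 1.05-fold higher in spleen. Il17a, below background in all pools but that of lymph node GFP-RFP+ cells, did not pass. The list test gave an adjusted p of 5.56e-12, 0.011 with a correlation estimated over the 8 arrays, and no call with an estimated correlation over the pools (adjusted p = 0.466).

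Receptors that direct T cell migration shifted in both directions. Of 24 homing receptor genes 16 rose and 4 fell (17 and 5 adjusted over the list alone; median 0.42). Cxcr4, the receptor for the chemokine CXCL12, was 5.63-fold and 5.49-fold higher, Cxcr6 3.17-fold and 4.92-fold, the oxysterol receptor gene Gpr183 3.66-fold and 3.51-fold, and Ccr10, a receptor of skin and mucosal homing, at least 3.47-fold in lymph node and 2.43-fold in spleen. A dimmer Gpr183 probe set was higher by 0.53 and 0.44. Ccr7, a receptor of lymph node homing, rose (2.11-fold and 2.42-fold), while Ccr9, a receptor of gut homing, fell (-0.65 ± 0.09). The list's adjusted p was 2.38e-07 and was lost with an estimated correlation (adjusted p = 0.0528 over the 8 arrays and 0.466 over the pools).

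Early response genes, which T cells switch on within an hour of a stimulus, were higher in the GFP-RFP+ cells of both organs. Of the 22 members 20 rose, 1 fell and 1 did not pass (20 and 2 adjusted over the list alone), with a median of 0.98. Beside Atf3, Fosb was 6.21-fold and 11.5-fold higher and the nuclear receptor gene Nr4a2 3.84-fold and 7.22-fold. The other Nr4a2 probe sets ranged from -0.27 to 3.76 in lymph node and from 0.59 to 4.29 in spleen. Ier3 was at least 2.82-fold and 6.26-fold higher. The activation marker Cd69 (2.25 ± 0.09) and Fos (0.59 ± 0.05) also rose, Myc fell (-0.51 ± 0.06), and Egr3 did not pass (-0.16 ± 0.06); these 4 were named after their values were seen. The list's adjusted p was 1.18e-23, 0.0459 with a correlation estimated over the 8 arrays, and no call with an estimated correlation over the pools (adjusted p = 0.466). A heat shock list, fixed after the files were seen, moved with it by less: 10 of 14 genes rose and 1 fell (11 and 1 adjusted over the list alone), with medians of 0.21 in lymph node and 0.28 in spleen.

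Proliferation genes were modestly higher. Of 22 cell cycle genes 13 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.32), among them the mitotic kinase gene Aurka (0.94 ± 0.16), Ccnb2 (0.89 ± 0.14), Rrm2 (0.72 ± 0.07) and the proliferation marker Mki67 (0.70 ± 0.07). The adjusted p was 1.15e-07 and was lost with an estimated correlation (adjusted p = 0.148 over the 8 arrays, 0.466 over the pools). Interferon response genes ranked lower in the GFP-RFP+ cells, with 1 of 16 up and 4 down (the same counts adjusted over the list alone; median -0.15). Gbp2 (-0.39 ± 0.05) and Igtp (-0.29 ± 0.06) fell and Rsad2 rose (0.52 ± 0.12). The list's adjusted p of 0.0291 was lost with an estimated correlation (adjusted p = 0.614 over the 8 arrays and 0.539 over the pools).

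Foxp3 and the genes described for thymic or peripheral Treg had mean log2 differences of a size under 1, by their brightest probe sets. Foxp3 (gene ID 20371) itself was 1.4-fold lower in lymph node and 1.58-fold lower in spleen in the GFP-RFP+ cells (-0.57 ± 0.06, adjusted p = 6.48e-05). Of 5 genes described as higher in thymic Treg, Swap70 fell (-0.53 ± 0.07) and Nt5e, which encodes the ectoenzyme CD73, rose (0.27 ± 0.05), with the same counts adjusted over the list alone. The 3 others did not pass: Ikzf2, which encodes Helios, differed by -0.12 ± 0.05 (adjusted p = 0.15), the semaphorin receptor gene Nrp1 by -0.05 ± 0.07 (adjusted p = 0.741) and Pdcd1 by 0.11 ± 0.11. Ikzf2 passed with quantile normalization added (-0.29, adjusted p = 0.00308), on 8 separate arrays (0.0352), with a replicate block (0.0491) and with duplicateCorrelation (0.00957). Over all alternatives its adjusted p ran from 0.00308 to 0.557. Other bright Nrp1 probe sets differed by 0.03 in lymph node and 0.35 in spleen, and by -0.05 and 0.33. A dimmer Nrp1 probe set was lower by -1.06 and -0.79. The list of 5 was not called (median -0.05, adjusted p = 0.654). Of the 2 genes described as higher in peripheral Treg, Igfbp4 fell (-0.80 ± 0.10, adjusted p = 0.000173) and Dapl1, which had a dim signal, differed by 0.53 ± 0.23 without passing. Of the other Igfbp4 probe sets above background, 3 also read lower in both organs, and 1 differed by -0.41 in lymph node and -0.01 in spleen. Adjusted over the list alone, 1 of them rose and 1 fell.

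Of 26 measured Treg signature genes, 12 rose and 8 fell (13 and 9 adjusted over the list alone; median 0.14, adjusted p = 0.133, percentile 99.6 among random lists). Gzmb, Klrg1 and Ctla4 were on the rising side. Gpr83, Ecm1 (-1.50 ± 0.07), Il2ra, which encodes the interleukin 2 receptor chain CD25 (-0.86 ± 0.12), and Ikzf4 (-0.65 ± 0.06) fell, the last 2 named after their values were seen. Genes that are low in Treg went both ways, 3 of 12 up and 3 down (6 and 5 adjusted over the list alone; adjusted p = 0.935, with a median of 0.14 and a test direction of lower). The phosphodiesterase gene Pde3b rose (1.25 ± 0.12), and Id3 (-0.78 ± 0.06) and Igfbp4 fell; Il2, at least 1.75-fold and 1.23-fold higher against background, did not pass. Of 17 naive and resting T cell genes 4 rose and 5 fell (4 and 8 adjusted over the list alone; median -0.14, adjusted p = 0.181, percentile 0.05 among random lists), with Ccr7 up and Igfbp4 and Bcl2 (-0.60 ± 0.09) down.

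Markers of other cells had no list past the camera threshold between the populations, but against random lists matched on level 3 of their medians ranked high in GFP-RFP+ cells. These were macrophage and monocyte (0.21, percentile 98.6), dendritic cell (0.19, percentile 98.9) and erythroid and platelet genes (0.32, percentile 98.8), with medians of 0.12, 0.15 and 0.13 when signals under background were set to it. Of 14 macrophage and monocyte genes 2 rose, Vcam1 (at least 3.27-fold in lymph node and 1.23-fold in spleen) and Lyz2 (0.53 ± 0.14), and 0 fell (adjusted p = 0.198). Of 11 B cell genes Cd22 rose (0.91 ± 0.11) and Cd79b fell (-0.61 ± 0.11), with an adjusted p of 0.935, a median of 0.04, a mean of -0.04 and a test direction of lower. Of 14 dendritic cell genes 4 rose and 1 fell (adjusted p = 0.181), the risers being Tcf4, H2-Aa, Cd74 and H2-Eb1. The lists of NK and innate-like lymphocytes (1 up, 1 down of 10, adjusted p = 0.935), neutrophils (0 of 9, adjusted p = 0.935), erythroid cells and platelets (1 up of 9, adjusted p = 0.181) and lymphoid stroma (0 of 11, adjusted p = 0.905) were not called. For these lists the counts adjusted over the list alone were the same. The neutrophil median was -0.01 with a test direction of higher, and the NK median was 0 with a mean of -0.03 and a test direction of lower. The 2 genes of CD8 T cells did not pass by their brightest probe sets, Cd8a at -0.11 ± 0.15 and Cd8b1 at -0.03 ± 0.11. Another Cd8a probe set, with a signal of 94.5 and 112.8 in GFP+RFP+ and 22.1 and 19 in GFP-RFP+ cells, was lower by -2.10 in lymph node and -2.57 in spleen, and 2 further Cd8a probe sets also read lower in both organs.

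The population difference was alike in the 2 organs where signals were bright. Across all genes the lymph node and spleen log2 differences correlated at r = 0.359 (rho = 0.364), and across the 10332 brighter genes at 0.881; genes are not independent replicates. Of the sum of squares among the 4 pools in the brighter genes, 64.4% lay between populations, 31.2% between organs and 4.4% in the difference between the organs' population effects. Over all genes these shares were 42.1%, 38.1% and 19.8%.

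**Figure D2:**
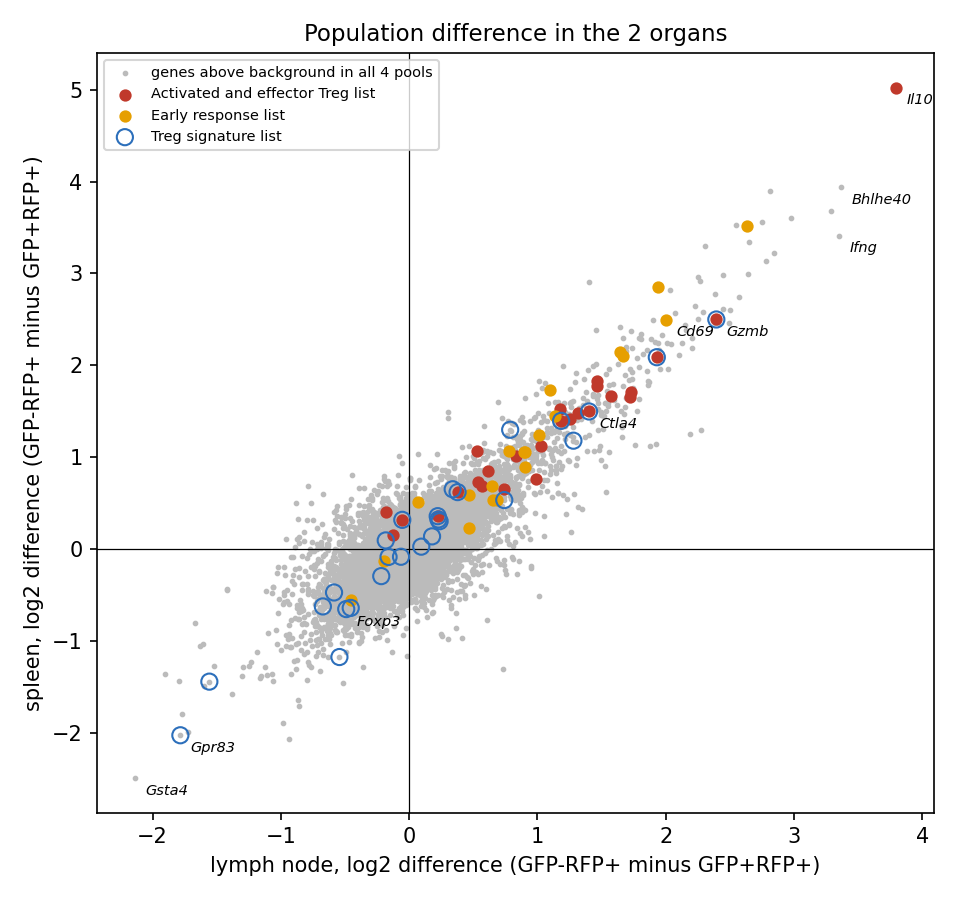
Log2 difference between GFP-RFP+ and GFP+RFP+ cells in lymph node (horizontal axis) and spleen (vertical axis) for the 12106 genes above background in all 4 pools (grey), with 3 gene lists marked. The activated and effector Treg genes (red) and early response genes (orange) lie mostly in the upper right, with medians of 1.18 and 0.98 over their full lists, while Treg signature genes (blue rings) spread to both sides.

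A test of that difference on the 8 technical arrays, which compares the 4 RNA pools and no animals, passed for 2 of 20665 genes, with 1373 at an unadjusted p under 0.05. Rgs16, a regulator of G protein signalling, was higher in GFP-RFP+ cells by 1.46 in lymph node and 2.38 in spleen (interaction 0.93 ± 0.10, adjusted p = 0.012); with 1 array left out it passed in 2 of 8 cases, with adjusted p from 0.0167 to 0.376. Dnah7b, a dynein heavy chain gene, was higher by 0.37 in lymph node and lower by -0.87 in spleen (interaction -1.24 ± 0.10, adjusted p = 0.00051), and passed in all 8 such cases. The count was 61 without the spleen GFP-RFP+ replicate 1 array, and 1 without any single lymph node array or spleen GFP+RFP+ replicate 1. Without the level trend limma called 0 genes, with 1209 at an unadjusted p under 0.05.

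The second comparison asked how spleen cells differed from lymph node cells within the same populations. The macrophage gene C1qa, the plasma cell gene Jchain, the B cell gene Cr2 and the red cell precursor gene Alas2 were far higher in spleen, in both populations, although the cells had been sorted as CD4+CD25+. The complement gene C1qa (gene ID 12259) was below background in both lymph node pools and at least 25.2-fold higher in spleen for GFP-RFP+ and 23.7-fold for GFP+RFP+ cells (adjusted p = 7.36e-09). Jchain (gene ID 16069), which encodes the chain that joins secreted IgM and IgA, was at least 92.8-fold and 50-fold higher (adjusted p = 3.93e-09), and Slc40a1 (gene ID 53945), the iron exporter ferroportin, at least 40.9-fold and 46.2-fold (adjusted p = 2.85e-09). The haem synthesis gene Alas2 was at least 21.5-fold and 11.7-fold higher, the neutrophil and monocyte gene S100a9 18.6-fold and 14.2-fold, and C1qc 13.6-fold and 11.4-fold. The immunoglobulin genes Ighg (at least 13.8-fold and 31-fold) and Iglv1 (37.2-fold and 7.01-fold) belong to families of near-identical copies, so their values are uncertain for a gene.

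In the other direction Wnt10a (gene ID 22409), a secreted Wnt ligand, was 7.6-fold lower in spleen for GFP-RFP+ and 5.38-fold lower for GFP+RFP+ cells (-2.68 ± 0.13, adjusted p = 5.11e-07). Bpifa2 was at least 2.03-fold and 3.79-fold lower. Of the other genes taken by the naming rule, Asb4, Taf7l2, Twist1, Sapcd1 and P2rx2 had bounds of at most 1.38-fold or none, and the last 3 did not pass. Gzmb (-1.14 ± 0.09) and Igfbp4 (-1.25 ± 0.10, or 0.04 and -0.37 by another probe set) were the remaining genes above background in all pools that were 2-fold lower in spleen in both populations, against 44 that were higher.

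Over all genes, 485 passed, 373 higher and 112 lower in spleen, and 178 and 12 of them by a log2 difference of 1 or more. Without a test, 1307 genes differed by 2-fold or more in GFP-RFP+ (811 higher, 496 lower) and 1146 in GFP+RFP+ cells (734 higher, 412 lower); 289 did so the same way in both, 242 higher and 47 lower, where independent lists would share 28.8 and 9.9, and 118 of the 289 had no pool above background. On the brighter genes alone the splits were 87 higher and 19 lower in GFP-RFP+ and 64 and 5 in GFP+RFP+ cells. Without the level trend 0 genes passed, with 1803 at an unadjusted p under 0.05, and with signals under background set to it 308 passed. The count was 310 without the spleen GFP-RFP+ replicate 1 array.

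**Figure D3:**
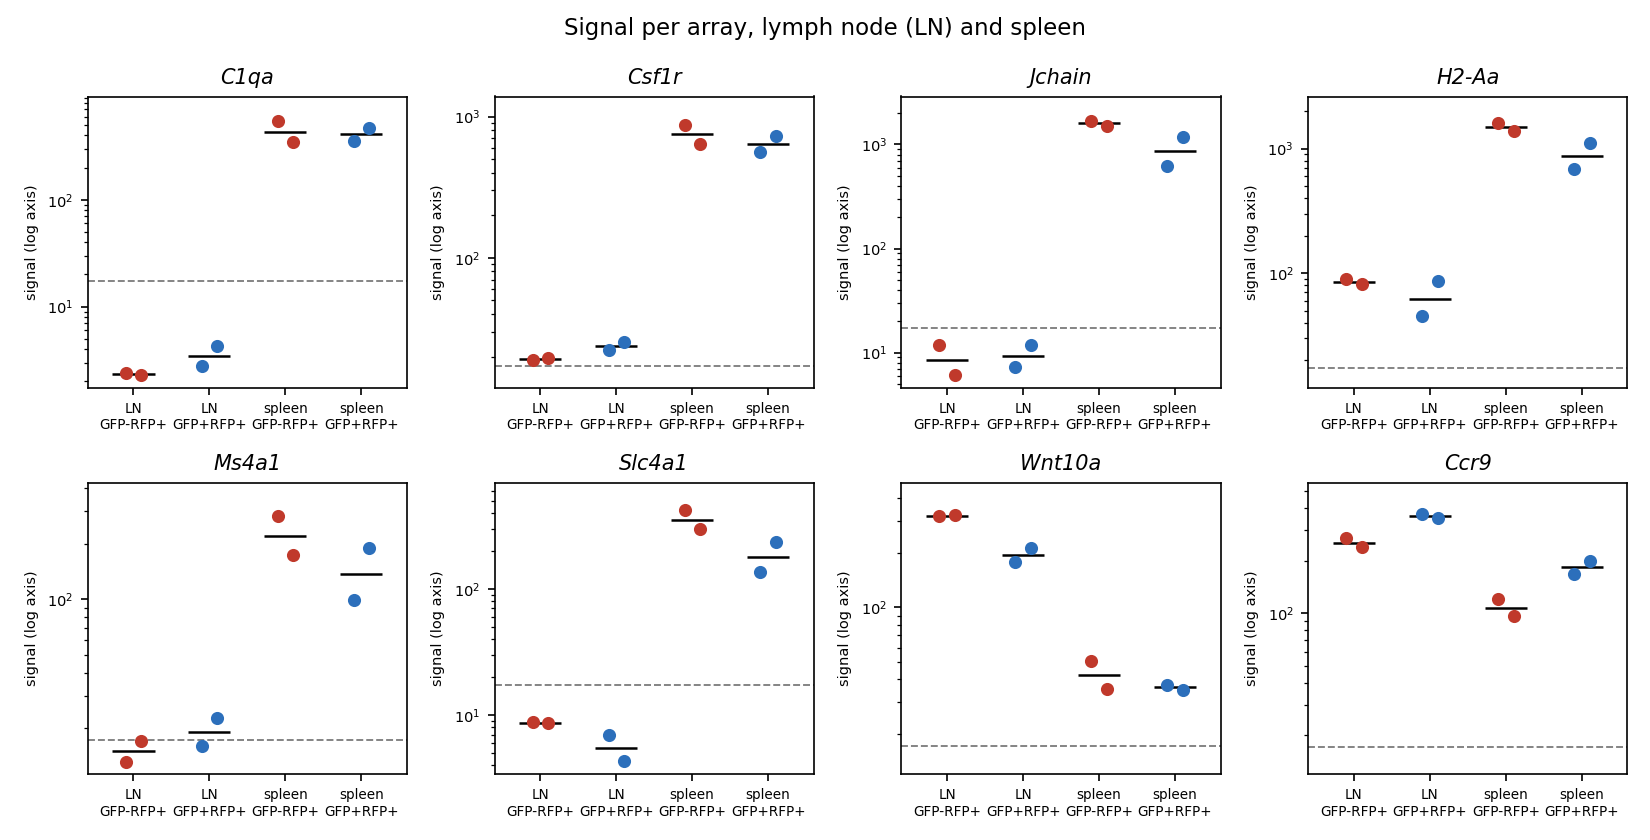
Signal of 8 genes on each of the 8 arrays, on a log axis, with 2 technical arrays (points) and their geometric mean (bar) for each population in lymph node (LN) and spleen; the dashed line is the background level of 17.22. C1qa, Csf1r, Jchain, H2-Aa, Ms4a1 and Slc4a1 lay higher on all spleen arrays than on all lymph node arrays, and Wnt10a and Ccr9 lay lower.

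Macrophage and monocyte genes led the organ difference. Of 14 genes 13 rose in spleen and 0 fell, also adjusted over the list alone, with a median log2 difference of 4.23, or 3.00 with signals under background set to it. Csf1r, the receptor for macrophage colony-stimulating factor, was 39.2-fold higher in GFP-RFP+ and 27-fold higher in GFP+RFP+ cells by its brightest probe set, while another, above background in all pools, differed by 0.41 and 0.45 on the log2 scale. Vcam1, an adhesion molecule of red pulp macrophages and stroma, was 12.3-fold and at least 32.6-fold higher, and the haem-degrading enzyme gene Hmox1 rose by 2.74 ± 0.13, named after its value was seen. The adjusted p was 4.8e-49, 0.0403 with a correlation estimated over the 8 arrays, and no call with an estimated correlation over the pools (adjusted p = 0.524).

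Of 11 B cell genes 6 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.88, or 0.71 with signals under background set to it). Cr2 was at least 4.82-fold and 3.59-fold higher, and Cd22 2.36-fold and 2.95-fold. The list's adjusted p was 3.62e-13, 0.0441 with a correlation estimated over the 8 arrays and no call with an estimated correlation over the pools (adjusted p = 0.524). Of 14 dendritic cell genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.52, or 0.31 so set). The class II genes H2-Aa (17.5-fold and 13.9-fold), H2-Ab1 (20.3-fold and 10.5-fold), H2-Eb1 (13.9-fold and 11.2-fold) and Cd74 (4.25-fold and 3.18-fold), which B cells and macrophages also express, made up the rise, with Cst3, and Ccr9 fell (-1.10 ± 0.09). The adjusted p was 7.86e-08 and was lost with an estimated correlation (adjusted p = 0.122 over the 8 arrays, 0.524 over the pools).

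The other myeloid, NK and red cell lists were called on few members. S100a8 and S100a9 were the neutrophil genes that rose, 2 of 9 (3 adjusted over the list alone; median 0.79, or 0.02 with signals under background set to it). The adjusted p of 2.44e-05 was 0.0441 with a correlation estimated over the 8 arrays and lost with an estimated correlation over the pools (adjusted p = 0.524). Fcer1g and Tyrobp, receptor adaptor genes that macrophages also express, were the 2 of 10 NK and innate-like lymphocyte genes that rose (also adjusted over the list alone; median 0.42, or 0.03 so set). That list had an adjusted p of 9.08e-05, 0.0441 over the 8 arrays and no call with an estimated correlation over the pools (adjusted p = 0.524). Alas2 and Slc4a1 were among the 3 of 9 erythroid and platelet genes that rose (also adjusted over the list alone; median 0.32, or 0.02 with signals under background set to it), with an adjusted p of 9.08e-05 that was lost with an estimated correlation (adjusted p = 0.16 over the 8 arrays, 0.574 over the pools). The lymphoid stroma list was not called (0 of 11, adjusted p = 0.483), and the CD8 genes did not pass (Cd8a 0.03 ± 0.15, Cd8b1 -0.31 ± 0.11; adjusted over the list alone, 1 of the 2 fell).

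T cell genes differed less between the organs. Cell cycle genes ranked lower in spleen, with 6 of 22 down, 0 up and 16 not passing (10 and 1 adjusted over the list alone; median -0.26), among them Ccnb2 (-0.70 ± 0.14) and Rrm2 (-0.45 ± 0.07); the adjusted p of 1.02e-09 was lost with an estimated correlation (adjusted p = 0.102 over the 8 arrays, 0.524 over the pools). Of 24 homing receptor genes 6 rose and 6 fell (8 and 7 adjusted over the list alone; adjusted p = 0.266, median at percentile 0.64 among random lists). Cxcr4 rose (0.62 ± 0.05), and Ccr9 and Ccr6 (-0.75 ± 0.08) fell. Klrg1 rose by 1.14 ± 0.08 and Gzmb fell, so that 3 activated and effector Treg genes rose and 5 fell of 28 (10 and 6 adjusted over the list alone; adjusted p = 0.938, with a median of -0.05, at percentile 0.45 among random lists, and a test direction of higher). T helper lineage genes ranked higher, 4 up and 1 down of 22 (7 and 2 adjusted over the list alone; median 0.08, percentile 95.9 among random lists, adjusted p = 0.0394), a call lost with an estimated correlation (adjusted p = 0.16 over the 8 arrays, 0.574 over the pools). All 5 thymic Treg marker genes missed the threshold over all genes, and 4 were higher adjusted over the list alone; their list was called higher (median 0.24, adjusted p = 0.000437), which was lost with an estimated correlation (adjusted p = 0.16 over the 8 arrays, 0.583 over the pools). Of the peripheral Treg genes Igfbp4 fell and Dapl1 did not pass (-0.24 ± 0.23), also adjusted over the list alone.

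Of 12 genes that are low in Treg 1 rose, 2 fell and 9 did not pass (1 and 3 adjusted over the list alone), and the list ranked lower by the test (adjusted p = 0.0305) with medians of -0.19 in GFP-RFP+ and 0.07 in GFP+RFP+ cells. Of 17 naive and resting T cell genes 1 rose, 3 fell and 13 did not pass (1 and 5 adjusted over the list alone), with a test direction of lower (adjusted p = 0.0305) and medians of -0.15 and 0.07. Both calls were lost with an estimated correlation (adjusted p = 0.496 and 0.403 over the 8 arrays, 0.638 for each over the pools). In both lists Il7r, the interleukin 7 receptor, rose (0.70 ± 0.05) and Igfbp4 fell. Foxp3 did not differ by the test (-0.04 ± 0.06, adjusted p = 0.877). The lists of Treg signature genes (2 up, 5 down of 26; 7 and 8 adjusted over the list alone; adjusted p = 0.0806), suppressive molecules (1 up, 1 down of 13; 2 and 2; adjusted p = 0.492), costimulatory and inhibitory receptors (1 up, 1 down of 18; 4 and 1; adjusted p = 0.0907), early response (1 up, 1 down of 22; 2 and 1; adjusted p = 0.247) and interferon response (1 up, 1 down of 16; 1 and 1; adjusted p = 0.823) were not called.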

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

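Tests of the other-spleen-cell and splenic macrophage explanations were chosen after the organ result was seen; the 3 tests on early response genes were set before their values were seen.

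The population effect differed between the organs for Rgs16 by 0.93 on the log2 scale (spleen minus lymph node) and for Dnah7b by -1.24, in an interaction test against technical spread. With each array left out in turn, Dnah7b passed in 8 of 8 cases and Rgs16 in 2; Rgs16 was higher in GFP-RFP+ cells of both organs, and Dnah7b went opposite ways. The poly-A spike controls, which no comparison uses, were brighter in GFP-RFP+ than in GFP+RFP+ arrays of spleen by 0.634 (mean log2 over 12 probe sets) and differed by -0.101 in lymph node; hybridisation spikes differed by 0.253 and -0.006.

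The first pattern weighed was the rise of early response genes in GFP-RFP+ cells of both organs. Signals at background level are argued against, because the share of the 22 genes above background in both GFP-RFP+ pools was 1. Stress during dissociation and sorting stayed open and cannot be told apart from activation: the larger of the heat shock medians was 0.28, between the bounds set in advance for and against it, with Hspa1a at 1.60 and Hspe1 at -0.23. Conventional T cells in the GFP-RFP+ gate may contribute, since Foxp3 was lower there by -0.49 in lymph node and -0.66 in spleen, past the bound set in advance. Lower Foxp3 per cell would give the same value, Ikzf2 was lower by less (-0.12 without passing, or -0.29 and past the threshold with quantile normalization, where Foxp3 was -0.65), and a difference in Treg origin or recent stimulation remains untested.

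The second pattern was the rise of genes from the macrophage, B cell, erythroid and neutrophil lists in spleen. Other spleen cells in the sorted fractions stay open: over members above background in at least 1 pool, many of them below it in lymph node, the list medians in GFP-RFP+ and GFP+RFP+ cells were 4.24 and 4.29 for macrophages, 1.16 and 0.73 for B cells, 1.95 and 1.01 for erythroid cells, and 0.1 and 0.57 for neutrophils. The lowest of these decides nothing, because its 6 genes went both ways (S100a9 at least 18.6-fold higher, against -0.17 for Mpo) and a lymph node signal of 108.3 for Ngp would hide a small share. Splenic macrophages or their RNA stay open as well: 8 further genes of red pulp and marginal zone macrophages had medians of 1.05 in GFP-RFP+ and 0.37 in GFP+RFP+ cells, the second between the bounds set for and against it, and 4 of them rose (Cd5l at least 19.5-fold and 16.8-fold, Treml4 at least 5.58-fold and 4.79-fold, Mertk by 1.26, against -0.16 for Siglec1, which did not pass). The sort on CD4 and CD25 should remove macrophages, C1qa reached a signal of 434.5 and Csf1r 750 in spleen GFP-RFP+ cells, and a difference between spleen and lymph node Treg themselves was not tested.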

How the results depend on the processing

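The floor at background, the fit without trend on the brighter genes and the set test over 8 arrays were chosen after seeing the data; the cause was not tested except where stated. Named genes that passed in the main fit kept their direction. Of 2036 pairs of a gene and a setting in each comparison, 126 for population and 110 for organ fell below the threshold, 38 and 71 rose past it, and 0 reversed. Several settings change the error of a gene and not its estimate, so they could not reverse a direction. These were separate arrays, the replicate block, duplicateCorrelation, the fit without trend and the level filter. Foxp3, for 1, stayed at -0.573 under each. A change of sign was counted only for genes that passed in the main fit. Of 296 pairs of a list and a setting these were 15, 32, 1, 7 and 0, by the same rule. Signal over background limits the dimmer genes.

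Genes past the threshold, 3272 for population and 485 for organ, became 0 and 0 without trend (prior degrees of freedom 1.4 against 9.6; unadjusted 3479 and 1803), 5664 and 1528 with duplicateCorrelation (consensus -0.274), 740 for organ on 8 separate arrays, 308 for organ with the floor, and 166 for organ (2679 for population) without trend on the brighter genes. Quantile normalization moved the median population difference from -0.007 to -0.039 and turned the split (1517 higher, 1805 lower), with 2788 calls shared, all in the same direction. Leaving out an array gave 2116 to 3909 and 310 to 711, the lowest without spleen GFP-RFP+ replicate 1. The interaction count of 2 became 0 without trend (unadjusted 1209), 5 on the 10332 brighter genes, and 1 to 61 with an array left out, 61 without spleen GFP-RFP+ replicate 1. With the technical number as a replicate block on 8 arrays, the counts were 3984, 684 and 3 (lists 8 and 9); same-numbered arrays had deviations correlated at -0.043 to 0.028 over all genes and -0.096 to 0.166 over the brighter genes, so the numbers were not taken to pair.

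Lists called, 8 for population and 11 for organ, became 0 and 0 with the correlation estimated over the pools (also 0 and 0 unadjusted). That test has 1 residual degree of freedom, so these losses say little on correlation between genes. With the 8 technical arrays taken as samples the counts were 4 and 4. By medians outside the central 95% of random lists they were 12 and 12 (10 higher and 2 lower, 7 and 5), which add and drop lists. Organ lists became 7 without trend, 7 on the brighter genes and 6 with both. With an array left out, where the lone array stands for its pool, they were 7 to 9 and 9 to 12.

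Counts at 2-fold (lymph node 1564, spleen 1579, both 442, organ in GFP-RFP+ 1307, in GFP+RFP+ 1146) became, in that order, 3353, 3436, 1206, 2523 and 2279 at 1.5-fold, 527, 489, 138, 475 and 371 at 3-fold, 292, 366, 240, 106 and 69 on the brighter genes, and 357, 462, 280, 212 and 134 with the floor. With an array left out they were 2237 to 2425, 2276 to 2529, 489 to 547, 2067 to 2215 and 1835 to 1910, since a pool with 1 array has no second array that could overlap. The correlation of 0.359 became 0.881 on the brighter genes, 0.795 with the floor, and 0.215 and 0.212 with technical replicates 1 and 2 split between the organs. The second deposited table was not run as an alternative, because its columns match no label and its values are the same.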

Other observations

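The families below were picked after the population values were seen. Of 18 genes for dual-specificity phosphatases, which switch off MAP kinases, with a pool above background, 7 rose in GFP-RFP+ cells, 0 fell and 11 did not pass (median 0.22), with Dusp14 higher by 3.49, Dusp10 by 2.82, Dusp4 by 2.20 and Dusp6 by 1.53. Of 15 Kruppel-like factor genes 6 rose, 0 fell and 9 did not pass, with rises for Klf4 (2.55), Klf6 (1.85), Klf10 (1.33) and Klf11 (0.77). Chemokine genes rose for 6 of 23, with Ccl1 at 1.55 and Ccl5 at 1.37 beside Cxcl2 and Cxcl10. Of 10 S100 genes 4 rose, S100a11 by 1.25 and S100a10 by 0.34 beside S100a4 and S100a6. With quantile normalization the counts were 7, 6, 5 and 4 higher, and 0 lower in each family.

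Of 62 cytosolic ribosomal protein genes 1 rose and 4 fell, with a median of 0.09 that turned to -0.05 with quantile normalization (0 and 10 called). Of 35 genes of mitochondrial complex I, 0 rose and 2 fell (median -0.08, or -0.15 and 11 lower with quantile normalization). Of 7 Gimap genes, GTPases of lymphocyte survival, 4 fell and 1 rose under either normalization (median -0.20, or -0.29 with quantile normalization), with Gimap1 at -0.30 as deposited.

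The spleen GFP-RFP+ pool had the least alike technical arrays: 43 of the 10332 brighter genes differed by 2-fold or more between them, against 6 to 8 in the other pools. Nr4a3 read 851.2 on replicate 1 and 2102.1 on replicate 2, and Gramd3 448.9 and 1053.9.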
